A study of Mus musculus with 10 samples.

How the data were processed

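RNA was sequenced from microglia sorted from the retinas of Cx3cr1GFP/+ mice, in which one copy of the fractalkine receptor gene is replaced by a green fluorescent protein (GFP) reporter that marks microglia and other myeloid cells. Per the labels' protocols, both retinas of an animal were pooled and digested with papain, and viable GFP-positive cells were sorted by flow cytometry. Libraries were made from low-nanogram amounts of total RNA with the SMARTer Ultra Low kit, which copies full-length polyadenylated RNA and does not mark strand, and were read in pairs on a NovaSeq. The 10 libraries fall into 3 groups named by the labels: 3 littermate controls (Control), 3 mice 4 weeks after streptozotocin (4wk STZ) and 4 mice 8 weeks after it (8wk STZ). Streptozotocin (STZ) destroys the insulin-producing beta cells of the pancreas and is used to make mice diabetic. Each library comes from a separate animal. The labels give one control set, and give neither the age of each control nor a library batch. The groups may therefore also differ in animal age.

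The deposited table of all genes holds raw read counts per gene, as whole numbers, per the file headers. The submitters' processing notes name bcl2fastq, STAR, Subread with featureCounts, Salmon, edgeR and limma, and the mouse build GRCm38. Which of these made the table, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Reads from genes that overlap on opposite strands, from near-identical paralogs and from pseudogenes can therefore be split or shared between them. A second deposited table holds the authors' own comparison of each STZ group with Control for 14475 genes, with the log2 fold change, the mean log2 CPM, a likelihood ratio score, the p-value and the FDR, per the file headers. That table repeats the raw counts for its genes. Of the numeric columns, 1, the number of transcripts per gene, was not used. The authors' comparison values were used only to set them beside the counts of calls obtained here.

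The table of all genes has 55774 entries, of which 287 repeat an Ensembl identifier with identical counts. After these were dropped, 55487 genes remained, of which 19211 had no read in any library. Library totals ran from 33266838 reads (4wk STZ 3) to 62903489 reads (8wk STZ 1). No pair of libraries within a group was alike enough to be 1 library deposited again, as the chi-square of their counts over its degrees of freedom was 52.7 or more. Intervals and floors given for genes with few reads come from reads summed over a group and cover counting error only. They leave out spread between animals. Amplified reads carry no molecular identifiers, which can make the intervals too narrow. Counts were scaled by TMM factors, filtered with filterByExpr by group, which left 18957 genes, and fitted with edgeR 4.0.16 in R 4.3.3 with 1 mean per group over all 10 libraries (7 residual degrees of freedom). Each contrast was tested with the robust quasi-likelihood F-test and Benjamini-Hochberg adjustment, and a call is an adjusted p below 0.05. The biological coefficient of variation was 0.564. CPM values are on the TMM scale and are given as mean ± SD over the libraries of a group (n = 3, 3 and 4). Standard errors (SE) belong to log2 fold changes. Coordinates and gene classes come from the GENCODE vM21 annotation of GRCm38, in which 99.88% of the tested genes were found.

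A set of 38 gene lists was fixed before the data were examined, covering microglial states, immune pathways, metabolism, stress, proliferation and markers of other cells that the gate or free RNA of the dissociated retina could bring. Of these, 36 had enough tested members for a set test. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count of 2) with a preset inter-gene correlation of 0.01, adjusted over the 36 lists of a contrast. Camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run beside it. With an estimated correlation no list passed in any of the 3 contrasts, and the smallest adjusted p was 0.941, 0.291 and 0.408 for 4wk STZ against Control, 8wk STZ against Control and 8wk STZ against 4wk STZ. For list members, calls are counted over all genes tested and adjusted over the list alone.

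Genes named in the text follow a rule fixed before the data were examined. It takes, per contrast, the 10 largest rises and the 10 largest falls (5 each for 8wk STZ against 4wk STZ) among called genes with a mean log2 CPM of at least 2 whose groups do not overlap, leaving out predicted genes, pseudogenes, Xist and Y-linked genes. It adds up to 4 members per list: those with the smallest p in the direction of a list that passed, the called members of other lists, or else the 2 most highly expressed. Where fewer than 5 genes were called, the 10 with the smallest p are given as values that did not pass. The text gives only part of the members that the rule takes from lists that did not pass, and 1 gene that the rule takes is not reported here, though the counts and lists include it, except the counts of values and genes picked out in the closing section. Genes outside the rule are said to be chosen after their values were seen.

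The steps were tested on simulated counts drawn from the means, spread and totals of the real libraries, with 100 genes changed 2-fold and 100 changed 4-fold. For 8wk STZ against Control, over 18197 simulated genes, 23% of the 2-fold and 42% of the 4-fold changes were called, with 1 false call. Among changed genes at a log2 CPM of 5 or more, 83.3% and 100% were called. For 4wk STZ against Control the shares were 23% and 37% over 18174 genes, and 83.3% and 100% among the well-expressed ones, with 4 false calls. For 8wk STZ against 4wk STZ they were 25% and 44% over 18197 genes, and 91.7% and 100%, with 3 false calls.

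Alternatives fixed beforehand were other scalings (RLE, library totals, upper quartile), no filter or a filter of 50 reads in 3 libraries, fits of only the groups compared, protein-coding genes only, Xist and Y-linked genes left out, each library left out in turn, the replicate number as a block, 1 surrogate variable (sva 3.50.0), limma-voom with quality weights, DESeq2 1.42.0 and a 2-fold threshold. Added after the data were examined were edgeR's likelihood ratio test, random thinning of every library to about the lowest total, and a fit without Control 3 and 4wk STZ 3. Simulations of unchanged groups against the shared controls under the stricter filter and without single libraries (8 each) were also added then. No library was excluded from the results given.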

Results

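Gene expression was measured in microglia sorted from the retinas of control mice and of mice made diabetic with STZ, 4 or 8 weeks after the drug. The comparisons ask how the transcripts of these cells differ from littermate controls at each time, and between the times. Total counts per library ran from 45656309 to 54312248 in Control (n = 3), 33266838 to 49051036 in 4wk STZ (n = 3) and 46143178 to 62903489 in 8wk STZ (n = 4). Microglial genes were among the most abundant: Cst3, the protease inhibitor cystatin C, stood at 22750 ± 3460, 20630 ± 2440 and 29830 ± 4680 CPM, and Csf1r, the receptor on which microglia depend for survival, at 10750 ± 584, 9435 ± 298 and 7747 ± 267 CPM. Transcripts of rod photoreceptors were present in every library. The 16 rod markers took 1.36 ± 0.0723% of reads in Control, 0.90 ± 0.159% in 4wk STZ and 0.558 ± 0.0733% in 8wk STZ. Across genes, the 8wk STZ libraries correlated with each other at r = 0.944 to 0.950, against 0.907 to 0.915 within Control and 0.907 to 0.919 within 4wk STZ. On the first 2 principal components Control 3 and 4wk STZ 3 lay apart from the other libraries, and the 4 8wk STZ libraries lay together on the first.

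After 4 weeks of diabetes no single gene passed the test, while rod photoreceptor markers were lower and cytosolic ribosomal protein genes higher as lists. Neither list passed with an estimated correlation (adjusted p = 0.941 for both). The lowest p belonged to Fcrls, a microglial Fc receptor-like gene, at 299.6 ± 7.99 CPM in 4wk STZ and 682 ± 81 CPM in Control (log2 fold change -1.19, SE 0.164, adjusted p = 0.196). Capg, an actin-capping protein of macrophages, stood at 332 ± 25.8 against 202 ± 27.4 CPM (log2 fold change 0.72), and Serpine2, a secreted protease inhibitor, at 891 ± 81.2 against 1342 ± 61.2 CPM (log2 fold change -0.59), both with an adjusted p of 0.196. Btla, an inhibitory immune receptor, was at 8.81 ± 0.455 against 0.641 ± 0.346 CPM (log2 fold change 3.78, adjusted p = 0.196). Serping1, the C1 inhibitor of complement, had 485 reads over the 4wk STZ libraries and 5 over Control, a ratio of 107 with a 95% counting interval of 45.6 to 332. 4930563E22Rik had 188 reads against none in Control, at least 55.8-fold higher by a 95% counting limit and 69.2-fold against a floor of 3 reads over the group. Part of its exonic sequence overlaps Med31 on the opposite strand. These limits for Serping1 and 4930563E22Rik leave out spread between animals, and neither gene passed the test. Cacfd1 and Taf9b were lower and Mtmr6 and Htra3 higher (log2 fold changes -1.78, -1.09, 0.69 and 1.04, adjusted p = 0.196 to 0.232). The count of 0 from edgeR's quasi-likelihood test stands beside 1849 genes at an unadjusted p below 0.05. Other tools called 0 (limma-voom), 244 (edgeR's likelihood ratio test) and 492 genes (DESeq2).

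Of the 36 lists, 2 passed at 4 weeks, and 4, 5 and 5 passed without Control 1, 2 and 3. All 16 rod markers were tested and none was called over all genes, while 12 had fallen when adjusted over the list alone. The list fell with a median log2 fold change of -0.65 (camera adjusted p = 3.86e-11, and adjusted p = 0.941 with an estimated correlation). Rom1, a membrane protein of rod outer segment discs, stood at 356 ± 55.5 against 595 ± 66.8 CPM, and Nrl, the transcription factor that specifies rods, at 22.3 ± 6.24 against 48.0 ± 5.89 CPM, neither passing on its own (adjusted p = 0.239 for both). The 82 tested ribosomal protein genes rose as a list with a median log2 fold change of 0.25, or 0.15 without 4wk STZ 2 (camera adjusted p = 3.13e-11, and adjusted p = 0.941 with an estimated correlation). None of them was called over all genes or adjusted over the list alone, and Rpl3, a large-subunit protein, was at 2160 ± 213 against 1674 ± 136 CPM (adjusted p = 0.349). The 13 mitochondrially encoded transcripts had a median log2 fold change of 8.69e-05. Lists of homeostatic microglia (median -0.11, adjusted p = 0.0718), lysosome (-0.14, 0.0649) and the unfolded protein response (-0.25, 0.0649) came nearest to passing, and all others had an adjusted p of 0.253 or more. Median and mean differed in sign for lipid handling, TGF-beta signalling, hypoxia response, mitochondrially encoded transcripts and B cell markers (0.15 and -0.33, and a median of 0.23 with the gene without a read in a group at its bound), and for T and NK cells the test pointed up while both were below 0.

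After 8 weeks of diabetes, 449 genes differed from Control, 184 higher and 265 lower, and 209 of them by 2-fold or more. Transcripts of rods, Müller glia and inner retinal neurons, mitochondrially encoded transcripts and genes of glycolysis and lysosomes were lower as lists, along with genes that mark resting microglia. None of these lists passed with an estimated correlation (adjusted p = 0.291 to 0.469). Single genes that were higher included Srsf2, Gadd45g, Lyz2 and Ccl3. Srsf2, an SR-family regulator of pre-mRNA splicing (chromosome 11, 116849901 to 116853094, minus strand, GRCm38), rose from 34.1 ± 2.33 to 196 ± 41.2 CPM (log2 fold change 2.52, SE 0.211, adjusted p = 0.000392). On the opposite strand, Mettl23 overlaps 15.6% of its exonic sequence and Mfsd11 9.74%. Mfsd11 had a log2 fold change of -0.20 (adjusted p = 0.48). No value is given here for Mettl23, the larger overlap, so reads shared with that gene are not ruled out. Plekhg2, an exchange factor for small GTPases, rose from 4.52 ± 1.56 to 22.8 ± 3.35 CPM, Gadd45g, a stress-induced gene, from 8.08 ± 3.12 to 34.5 ± 5.97 CPM, and Tstd1 from 1.33 ± 0.544 to 12.4 ± 0.952 CPM (adjusted p = 0.00343, 0.0115 and 0.00853). Tstd1 shares 23.1% of its exonic sequence with Usf1, at a log2 fold change of 0.67 (adjusted p = 0.112). The list of largest rises also held Cdca2 and Fbxo5, which act in cell division, Cd200r4, a receptor of the CD200 receptor family, Paxbp1, and the lysozymes Lyz2 and Lyz1, close paralogs whose split of reads is uncertain. Lyz2 rose from 311 ± 134 to 1214 ± 408 CPM (log2 fold change 1.97, SE 0.379, adjusted p = 0.0241).

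The number of calls at 8 weeks was lower whichever library was left out: 255, 210 and 238 genes without Control 1, 2 and 3, and 223, 253, 206 and 213 without 8wk STZ 1 to 4. It was 275 without Control 3 and 4wk STZ 3 together. The groups did not overlap for 16.9% of tested genes, against 5.71% by chance. Of the 62 called genes that the rule names, 27 were called in each of these 7 fits, among them Srsf2, Plekhg2, Gadd45g and Tstd1, and the other 35 had a highest adjusted p of 0.0546 to 0.142. Lyz2 (adjusted p up to 0.064, without 8wk STZ 4), Lyz1 (0.123, without Control 2), Cdca2 (0.134, without Control 2), Fbxo5 (0.0693, without Control 2), Cd200r4 (0.0674, without 8wk STZ 2) and Paxbp1 (0.0737, without Control 2) were lost in at least 1 of them. In this order, they were called in 2, 0, 1, 4, 2 and 1 of the 7 fits. With library totals as the only scaling, 66% of calls were rises, with upper-quartile scaling 30.9%, and with TMM 41%. Of the 36 lists, 11 passed. Among the 35 splits of these 7 libraries, 12 gave 11 or more lists, and 1, the real one, gave 449 or more genes.

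**Figure D1:**
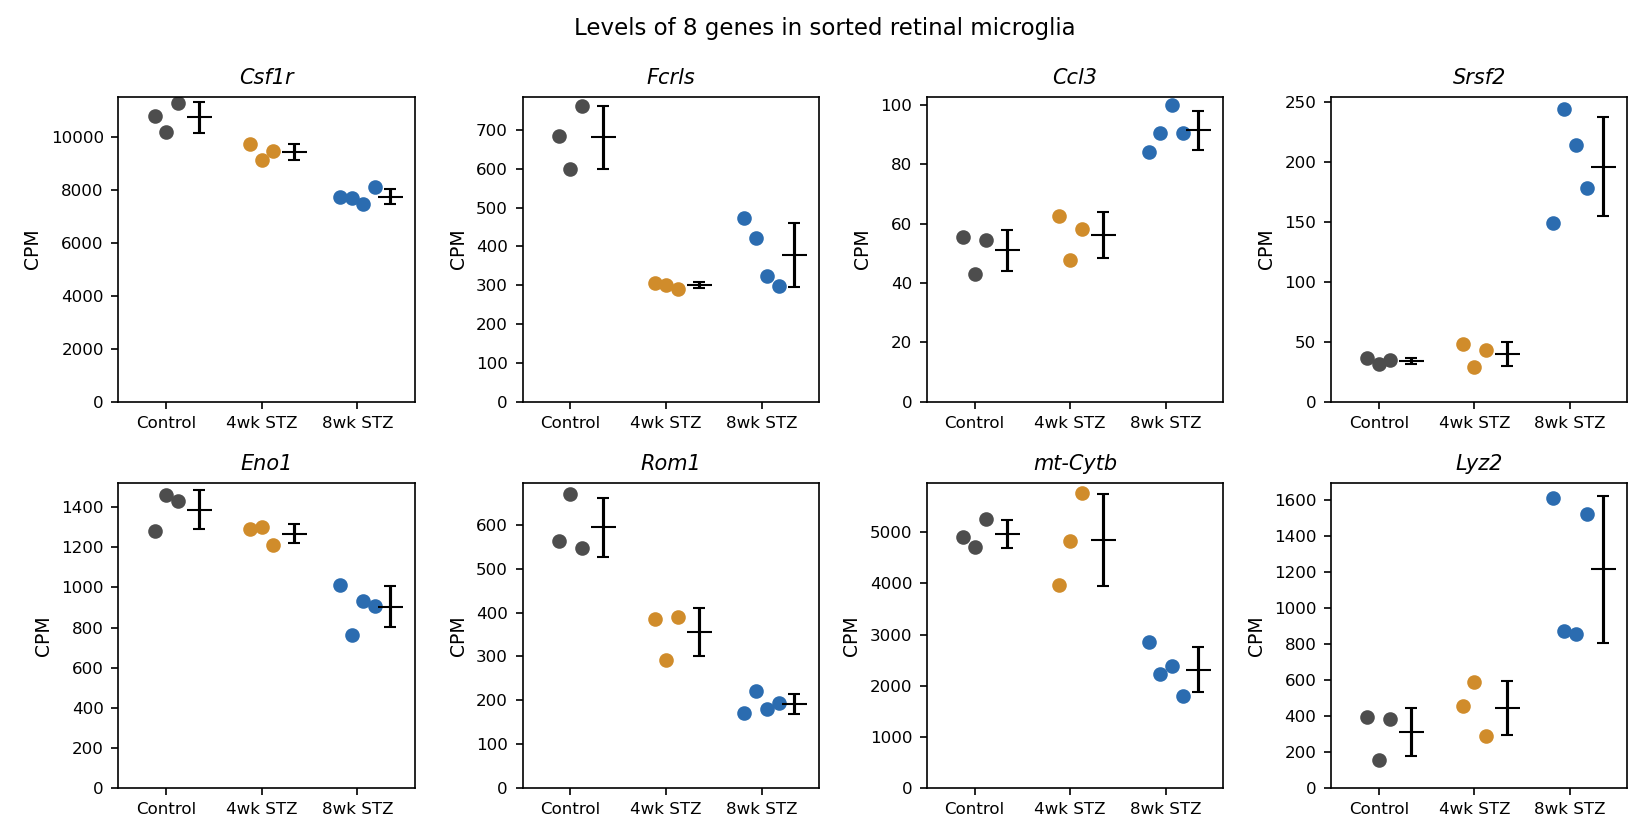
Levels of 8 genes (CPM, linear axes from 0) in each library of the Control, 4wk STZ and 8wk STZ groups, with points for libraries and bars for the mean ± SD. Srsf2 lies between 149 and 244 CPM in the 8wk STZ libraries and at 48.4 CPM or less in the others, and Csf1r has group means of 10750, 9435 and 7747 CPM.

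Homeostatic microglial genes fell as a list at 8 weeks, while 2 genes of disease-associated microglia rose. Of the 27 homeostatic genes, 2 rose and 5 fell (3 and 13 adjusted over the list alone), with a median log2 fold change of -0.28 (camera adjusted p = 0.00796, and adjusted p = 0.469 with an estimated correlation). Csf1r fell to 7747 ± 267 from 10750 ± 584 CPM (log2 fold change -0.47, SE 0.0641, adjusted p = 0.00525), and shares 15.1% of its exonic sequence with Hmgxb3 on the opposite strand. The 2 that rose, named after their values were seen, were Siglech, from 818 ± 114 to 1410 ± 49.2 CPM, and Bin1 (adjusted p = 0.0135 and 0.0449), which were not refitted with libraries left out. P2ry13, a purinergic receptor of resting microglia, Fcrls, and Tmem119, a membrane protein that marks microglia, also fell (log2 fold changes -0.59, -0.85 and -0.44). With library totals as the only scaling this list did not pass (median -0.18, adjusted p = 0.059). Without Control 3 the list did not pass either (median -0.18, adjusted p = 0.0654), nor did P2ry13 (0.0546) and Fcrls (0.0659), and Tmem119 was lost without Control 2 (0.0775). With each of 7 libraries left out in turn, P2ry13 was called in 5 fits, Fcrls in 4 and Tmem119 in 2. Of the 24 disease-associated genes, 2 rose and none fell (7 and 1 adjusted over the list alone), and the list did not pass (median 0.26, adjusted p = 0.141). The risen genes were Lyz2 and Clec7a, the receptor Dectin-1, which stood at 402 ± 35.6 against 288 ± 34.2 CPM (adjusted p = 0.0382, and 0.107 without Control 2). In 8wk STZ 1 to 4, Lyz2 was at 1610, 871, 853 and 1520 CPM. The border macrophage gene Mrc1, chosen after its values were seen, was at 86.9, 49, 6.9 and 112 CPM. Its mean did not rise (63.7 against 72.7 CPM in Control). Whether other myeloid cells of the gate gave the rise of Lyz2 was not tested. Ccl3, a chemokine of activated microglia, rose from 51.0 ± 6.97 to 91.4 ± 6.66 CPM (log2 fold change 0.84, SE 0.134, adjusted p = 0.0113) and was called whichever library was left out. It was the 1 called gene of 20 cytokines and chemokines (3 risen adjusted over the list alone), whose list did not pass (median 0.33, adjusted p = 0.125).

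Mitochondrially encoded and glycolytic transcripts were lower at 8 weeks as lists, though not with an estimated correlation (adjusted p = 0.291 for both). Of the 13 mitochondrially encoded transcripts, which code for subunits of the respiratory chain and ATP synthase, 9 fell over all genes and all 13 adjusted over the list alone, and none rose. Their median log2 fold change was -1.07 (camera adjusted p = 1.16e-14, and adjusted p = 0.291 with an estimated correlation), and their share of reads was 0.830 ± 0.128% in 8wk STZ against 1.41 to 1.56% in the Control libraries. mt-Cytb, cytochrome b, fell from 4958 ± 274 to 2314 ± 437 CPM (mitochondrial genome, 14145 to 15288, adjusted p = 0.00617), and mt-Nd1, mt-Co3 and mt-Atp6 fell by 1.09, 1.07 and 1.13 on the log2 scale. Near-identical copies of part of the mitochondrial genome lie on chromosome 1, and their summed reads had a log2 fold change of -1.05. In contrast, of the 75 nuclear genes of oxidative phosphorylation only Sdha, a subunit of succinate dehydrogenase, was called (1 fallen adjusted over the list alone), from 410 ± 25.7 to 305 ± 4.02 CPM (adjusted p = 0.0164, and 0.0613 without Control 2). That list had a median of -0.00207 and did not pass (adjusted p = 0.483). Of 25 genes of glycolysis and glucose transport, 7 fell and none rose (13 and 1 adjusted over the list alone), with a median of -0.37 (camera adjusted p = 3.86e-06, and adjusted p = 0.291 with an estimated correlation). Hk1, Aldoa, Eno1 and Pkm, which code for hexokinase, aldolase, enolase and pyruvate kinase, fell by 0.70, 0.59, 0.62 and 0.63 on the log2 scale. Whether the falls in glycolysis genes come from less retinal RNA in these libraries, rather than from microglia, was not tested. In the same libraries the 16 rod markers took 0.558 ± 0.0733% of reads, against 1.36 ± 0.0723% in Control, and ribosomal RNA genes 1.39 ± 0.296% against 2.09 ± 0.101%. After thinning to about the lowest total they held 23704 ± 492 genes with a read, against 22349 ± 96.2 in Control.

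**Figure D2:**
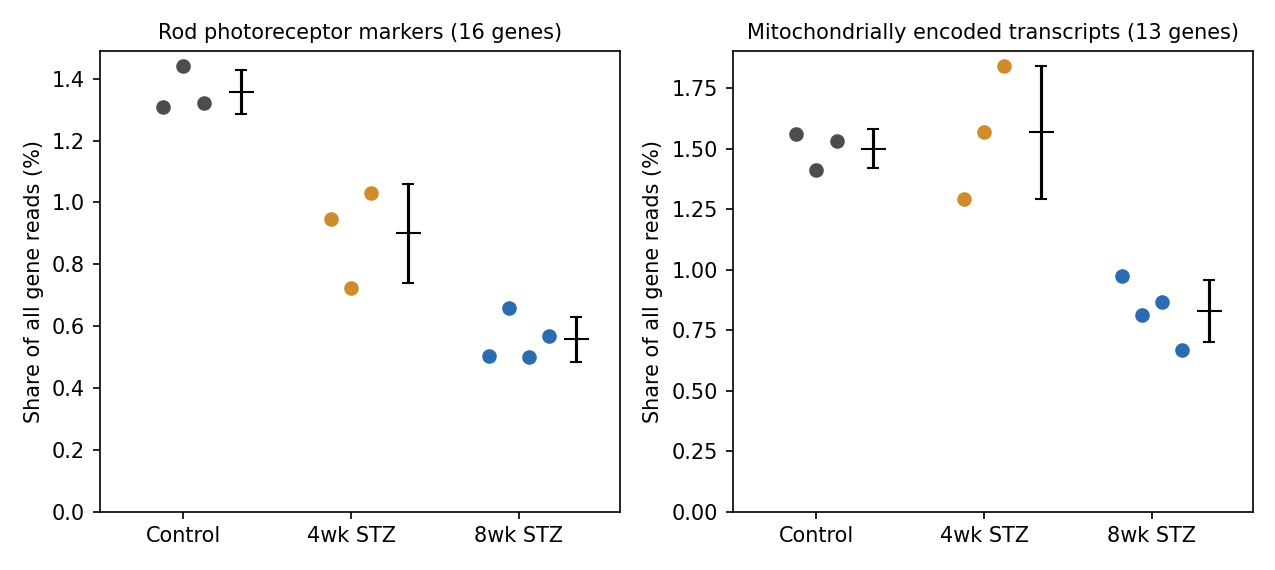
Share of all gene reads (%, axes from 0) taken by 16 rod photoreceptor markers (left) and 13 mitochondrially encoded transcripts (right) in each library, with the mean ± SD of each group. Rod markers averaged 1.36%, 0.90% and 0.558% in Control, 4wk STZ and 8wk STZ, and mitochondrially encoded transcripts took 1.41 to 1.56% in the Control libraries and averaged 1.57% and 0.830% in 4wk STZ and 8wk STZ.

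Markers of rods, Müller glia and inner retinal neurons were lower at 8 weeks as lists, though not with an estimated correlation (adjusted p = 0.291 to 0.343). All 16 rod markers fell, over all genes and adjusted over the list alone, with a median log2 fold change of -1.44 (camera adjusted p = 6.67e-25, and adjusted p = 0.291 with an estimated correlation). Rom1 (chromosome 19, 8927391 to 8929356, minus strand) fell from 595 ± 66.8 to 192 ± 22.3 CPM (log2 fold change -1.63, SE 0.13, adjusted p = 0.000392), and Gnat1, Pde6g and Nrl fell by 1.55, 1.45 and 1.71 on the log2 scale. Of 16 markers of Müller glia and astrocytes, 5 fell (9 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 4.23e-06, and adjusted p = 0.343 with an estimated correlation). They included Slc1a3 and Slc1a2, which take up glutamate, and Clu, clusterin, which stood at 55.0 ± 26.1 against 190 ± 65.5 CPM. Of 12 bipolar cell markers none was called over all genes and 5 had fallen adjusted over the list alone, with a median of -1.31 (camera adjusted p = 8.91e-05, and adjusted p = 0.291 with an estimated correlation). Of 20 markers of amacrine, horizontal and ganglion cells 3 fell (4 adjusted over the list alone), with a median of -0.49 (camera adjusted p = 0.00414, and adjusted p = 0.291 with an estimated correlation). Snap25, a synaptic vesicle fusion protein, fell from 108 ± 2.68 to 46.3 ± 7.40 CPM (adjusted p = 0.0015), and Syt1 fell by 1.19 on the log2 scale. Without Control 2 this list did not pass (adjusted p = 0.0642, median -0.00209), and its median was -0.32 without a filter and -0.24 in thinned libraries. Of 10 cone markers 1 fell (1 adjusted over the list alone), Guca1a, a calcium sensor shared by rods and cones, from 6.53 ± 0.916 to 2.14 ± 0.419 CPM. The cone list had a median of 0.25, a mean of -0.05, and did not pass (adjusted p = 0.77). Slc1a3 (0.0748, without Control 3), Slc1a2 (0.0783, without Control 3), Clu (0.0982, without Control 3) and Guca1a (0.0841, without Control 2) were among the calls lost when a library was left out. Vtn, vitronectin, the 1 called gene of 9 markers of pericytes, smooth muscle and fibroblasts (1 risen and 1 fallen adjusted over the list alone), fell from 145 ± 14.9 to 48.8 ± 5.56 CPM (adjusted p = 0.000753). That list did not pass (median -0.18, camera adjusted p = 0.341), so the fall of Vtn does not stand for these cells as a set. The other largest falls were Fhl1, Abca8a, Ttll11, Gpr37, Tubb4a, Impg1, Gnao1 and Mapk8ip2, by 1.74 to 2.72 on the log2 scale. Impg1, a component of the matrix around photoreceptors, and Gnao1, a G protein subunit abundant in neurons, were called whichever library was left out, and the other 6 were not (adjusted p from 0.078 for Abca8a without 8wk STZ 4 to 0.142 for Tubb4a without Control 2).

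Lysosomal genes fell at 8 weeks and interferon, immediate early and cell cycle genes rose, as lists that did not pass with an estimated correlation (adjusted p = 0.341 to 0.562). Of 32 lysosomal genes, 5 fell and none rose (10 and 2 adjusted over the list alone), with a median of -0.18, or -0.08 with library totals as the only scaling (camera adjusted p = 0.000561, and adjusted p = 0.421 with an estimated correlation). Atp6ap1, an accessory subunit of the proton pump that acidifies lysosomes, fell from 1140 ± 98.2 to 755 ± 16.7 CPM (adjusted p = 0.00359). Npc1, which exports cholesterol from lysosomes, Tpp1, a peptidase, and Ctsl, cathepsin L, fell by 0.64, 0.54 and 0.34. Their highest adjusted p came without Control 3 (0.0917, 0.0973 and 0.124). With each of 7 libraries left out in turn, Npc1 and Tpp1 were called in 2 fits each and Ctsl in 0. Of 30 interferon response genes none was called in either count, and the list rose with a median of 0.49 (camera adjusted p = 0.000403, and adjusted p = 0.562 with an estimated correlation; 0.0648 without Control 1). That median was 0.92 without Control 2 and 0.28 without 8wk STZ 2. Mx1, an antiviral GTPase, stood at 27.4 ± 14.8 against 4.64 ± 1.10 CPM (adjusted p = 0.0843). Of 28 genes of the immediate early and dissociation response, 1 rose and none fell (4 and 1 adjusted over the list alone), with a median of 0.32 (camera adjusted p = 0.0218, and adjusted p = 0.509 with an estimated correlation). The risen gene was Zfp36, which destabilises cytokine mRNA, from 316 ± 71.2 to 667 ± 69.5 CPM (adjusted p = 0.017, and 0.0669 without Control 3). This list, which papain digestion and sorting can raise, did not pass without Control 2 (adjusted p = 0.205), without Control 3 or with 1 surrogate variable (0.0659), and had a median of 0.52 without Control 1. Whether digestion and sorting also raised genes outside the list, such as Ccl3 and Gadd45g, was not tested. Of 30 cell cycle genes none was called over all genes and 2 had risen adjusted over the list alone, with a median of 1.11 (camera adjusted p = 8.91e-05, and adjusted p = 0.341 with an estimated correlation). Top2a, the topoisomerase of dividing cells, stood at 29.7 ± 9.09 against 9.67 ± 2.99 CPM (adjusted p = 0.0656).

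Other lists did not pass at 8 weeks, though some held called genes. Of 27 genes of the unfolded protein response, Calr, calreticulin, fell (509 ± 90.4 to 299 ± 23.8 CPM, adjusted p = 0.00887), and Ddit3, the stress transcription factor CHOP, and Ppp1r15a rose (adjusted p = 0.0449 and 0.0431). The list had a median of -0.20 (adjusted p = 0.108; 2 risen and 3 fallen adjusted over the list alone), and Ddit3 and Ppp1r15a were not called when any 1 library was left out (0.139, without Control 3, and 0.133, without Control 2). Of 27 genes of lipid handling, 3 fell (3 risen and 3 fallen adjusted over the list alone): Lpcat3, Scd2 and Abcg1, a cholesterol exporter, by 0.69, 1.10 and 0.85 (median -0.06, adjusted p = 0.77; Scd2 0.0959 and Abcg1 0.107 without Control 3). Single genes fell in the lists of NF-kB targets (Gpr84; median 0.07, adjusted p = 0.948), pattern recognition (Tlr9; 0.03, 0.77), MHC class I (Tapbp; 0.21, 0.36), renin-angiotensin (Atp6ap2; -0.24, 0.203) and TGF-beta signalling (Nrros; -0.16, 0.169). Gpr84 and Nrros had their highest adjusted p without Control 2 (0.110 and 0.0963) and Tlr9, Tapbp and Atp6ap2 without Control 3 (0.114, 0.0669 and 0.111). With each of 7 libraries left out in turn, Nrros, Tlr9 and Atp6ap2 were called in 0 fits, Gpr84 in 2 and Tapbp in 3. Adjusted over the list alone, these lists had 1, 6, 1, 1 and 1 fallen genes, and pattern recognition also had 4 risen.

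Apart from Vtn, no gene was called over all genes in the remaining lists at 8 weeks. Complement and phagocytic receptors had a median of -0.10 (adjusted p = 0.0518; 8 fallen adjusted over the list alone), and C1qb, part of the first complement component, was at 10250 ± 985 against 9012 ± 714 CPM. B cell markers had a median of 0.77 (0.0531), MHC class II 0.37 (0.36), hypoxia response -0.09 (0.274; 2 fallen adjusted over the list alone), cholesterol synthesis -0.16 (0.149; 2 fallen), oxidative stress and NRF2 targets 0.02 (0.859) and vascular and growth factors 0.18 (0.274). Cytosolic ribosomal proteins had a median of -0.06 (0.627), border macrophages -0.19 (0.36), monocytes 0.30 (0.77), T and NK cells -0.73 (0.781), endothelial cells 0.13 (0.859), pericytes, smooth muscle and fibroblasts -0.18 (0.341), and retinal pigment epithelium and melanocytes 0.72 (0.996; 1 fallen). Neutrophil and erythrocyte markers each had 2 tested genes and were given no set test. Median and mean differed in sign for complement, lipid handling, border macrophages and pericytes, and for pattern recognition the test pointed down while both were above 0.

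**Figure D3:**
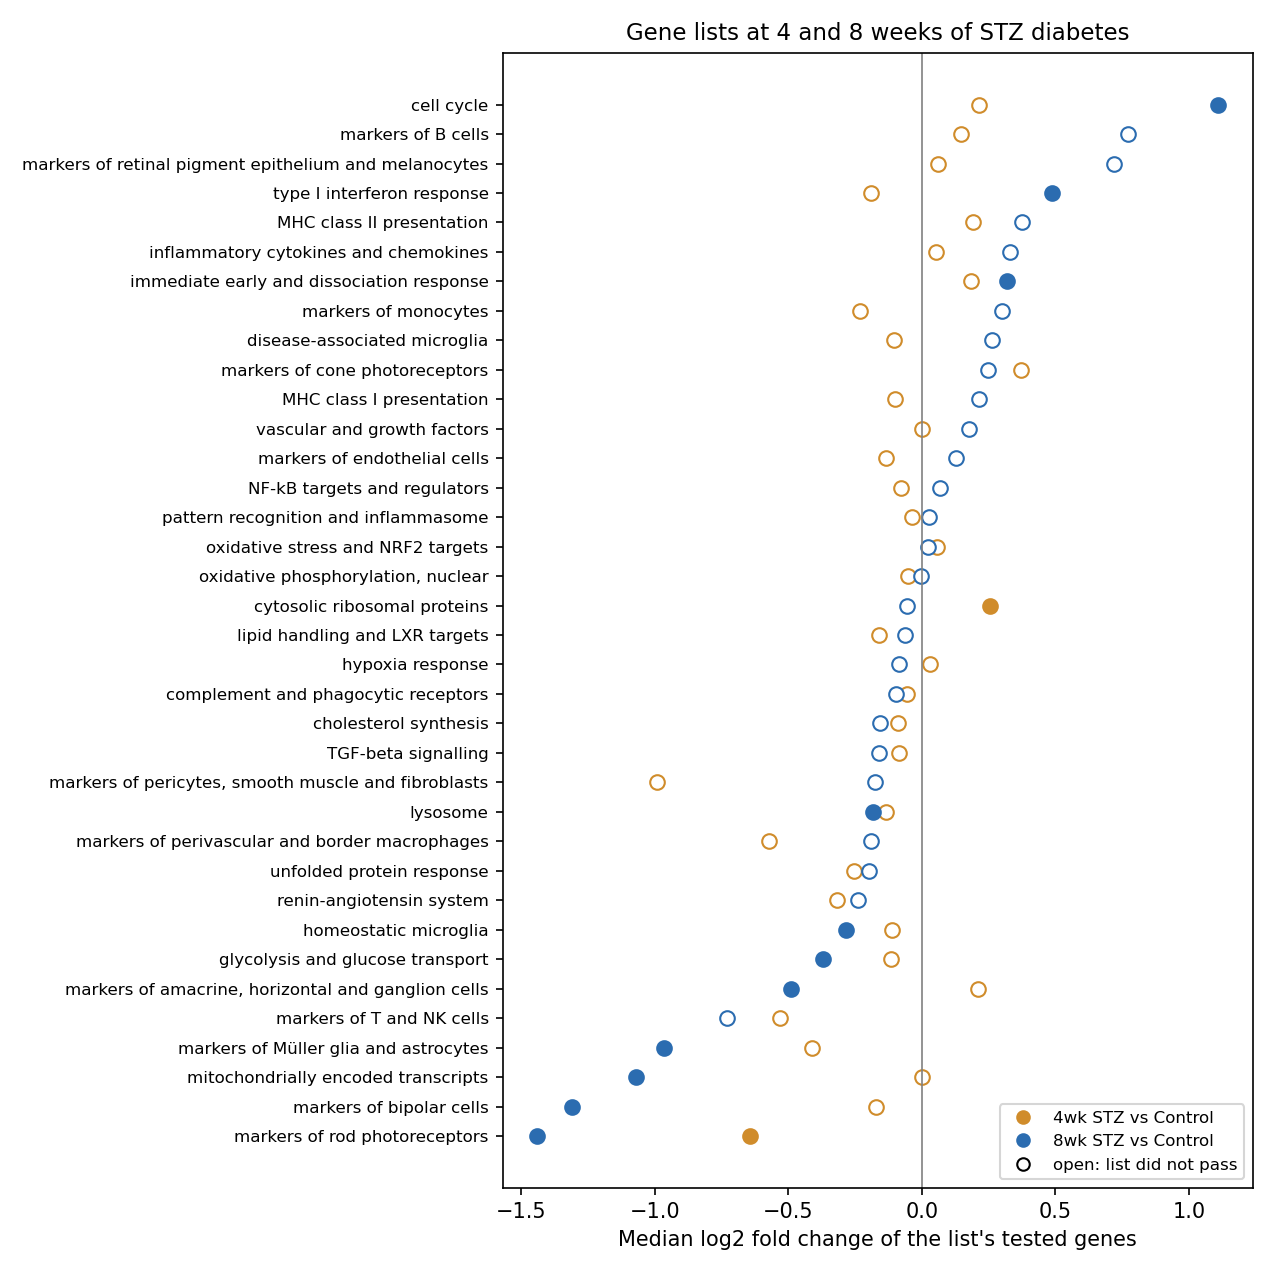
Median log2 fold change of the tested genes of 36 lists (linear axis) against Control, at 4 weeks in orange and at 8 weeks in blue. Filled points passed camera with a preset correlation, 2 lists at 4 weeks and 11 at 8 weeks, and none passed with an estimated correlation.

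Between 8 and 4 weeks of diabetes, 174 genes differed, 75 higher and 99 lower at 8 weeks, 69 of them by 2-fold or more. Srsf2 rose from 40.1 ± 10.0 to 196 ± 41.2 CPM (log2 fold change 2.29, SE 0.209, adjusted p = 0.00216), and Rgl2, an exchange factor for Ral GTPases, from 29.4 ± 4.62 to 92.3 ± 7.71 CPM (log2 fold change 1.65, SE 0.131, adjusted p = 0.000978). These were the 2 of 27 called genes named by the rule that passed whichever library was left out, and the other 25 had a highest adjusted p of 0.0544 (Snap25, without 4wk STZ 2) to 0.151 (Ccl2, without 4wk STZ 3). Ccnl1, a cyclin that acts in splicing, rose from 12.9 ± 4.20 to 54.9 ± 11.4 CPM (adjusted p = 0.0166, and 0.0811 without 4wk STZ 3). Plekhg2 and Nadsyn1, an enzyme of NAD synthesis, rose by log2 fold changes of 1.69 and 1.99, and Ndnf, Impg1, Gpm6b, Dpysl4 and Cadm2 fell by 1.57 to 2.35. Chemokines Ccl2, from 14.7 ± 3.54 to 39.9 ± 6.80 CPM, and Ccl3 rose (adjusted p = 0.0405 for both, and up to 0.151 without 4wk STZ 3 and 0.127 without 8wk STZ 3). Neither chemokine was called when any 1 library was left out. Apoe, a lipid carrier raised in disease-associated microglia, stood at 11750 ± 6480 against 3870 ± 1330 CPM and did not pass (adjusted p = 0.14).

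Of the 36 lists, 9 passed between the times. Of the 13 mitochondrially encoded transcripts 7 fell (12 adjusted over the list alone; median -0.98, camera adjusted p = 2.23e-15, and adjusted p = 0.408 with an estimated correlation), with mt-Cytb at 4851 ± 905 and 2314 ± 437 CPM. Of 25 glycolysis genes 2 fell, Hk1 and Eno1 (7 adjusted over the list alone; median -0.26, adjusted p = 4.75e-05, and adjusted p = 0.428 with an estimated correlation). Of 16 rod markers 6 fell (15 adjusted over the list alone), Rom1 from 356 ± 55.5 to 192 ± 22.3 CPM, and the list median was -0.76 (adjusted p = 6.67e-14, and adjusted p = 0.408 with an estimated correlation). Markers of Müller glia (median -0.67, none called, 6 fallen adjusted over the list alone), bipolar cells (-1.06, or -1.64 without 8wk STZ 2, none called, 3 fallen) and amacrine, horizontal and ganglion cells (-0.91, 2 fallen, 4 adjusted over the list alone) fell as lists. With an estimated correlation their adjusted p = 0.475, 0.408 and 0.408. Ribosomal protein genes fell with a median of -0.28, or -0.17 without 4wk STZ 2 (none called, 19 fallen adjusted over the list alone; adjusted p = 2.95e-12, and adjusted p = 0.606 with an estimated correlation). Interferon response genes (median 0.55) and cell cycle genes (median 0.66) rose as lists with no called member in either count (adjusted p = 0.642 and adjusted p = 0.469 with an estimated correlation), and without 4wk STZ 3 the cell cycle list did not pass (median 0.44, adjusted p = 0.0519). Without 4wk STZ 3, mt-Cytb (0.0821), Hk1 (0.0926), Rom1 (0.0926), Vtn (0.095) and Lamp2 (0.149) were lost, and without 4wk STZ 2 Eno1 (0.132) and Sdha (0.107). With each of 7 libraries left out in turn, Hk1, Eno1 and Sdha were called in 0 fits. Lamp2 was called in 1 fit, mt-Cytb in 2, and Rom1 and Vtn in 3 each. The other 27 lists did not pass. Median and mean differed in sign for complement, hypoxia response, the unfolded protein response and T and NK cells, and for nuclear oxidative phosphorylation, cholesterol synthesis and retinal pigment epithelium the test pointed down while both were above 0. Among the members of lists that did not pass, Lamp2, a lysosomal membrane protein, Sdha and Vtn fell, and Ccl2 and Ccl3 rose.

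Single libraries weighed on the number of genes called between the times. It was 118, 41 and 13 without 4wk STZ 1, 2 and 3, and 52, 45, 34 and 14 without 8wk STZ 1 to 4. It was 6 without Control 3 and 4wk STZ 3 together. With library totals as the only scaling 70.8% of calls were rises, with upper-quartile scaling 31.2%, and with TMM 43.1%. Of the 35 splits of these libraries 13 gave 9 or more lists, and 1, the real one, gave 174 or more genes.

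Fold changes at 4 and 8 weeks against the same controls correlated across the 18957 genes at r = 0.602, and 67.5% had the same sign. Genes are not independent replicates, and unchanged groups simulated against these 3 controls gave r = 0.542 (0.518 to 0.565 in 20 simulations) and 67.9%. The covariance was 0.821, against 0.487 simulated, a difference of 0.334. Simulated anew in each setting, this difference was 1.04, 1.06 and 0.922 without Control 1, 2 and 3, 0.551, 0.494 and 0.619 without 4wk STZ 1, 2 and 3, and 0.109 with the stricter filter, so its size is not settled. The simulated groups also share their controls, but every group was drawn from the observed Control means. A gene with few or no Control reads was thus simulated low in all groups. The simulated covariance can therefore be too low, and part of the difference may come from this. The 3 controls cannot be split into parts of 2 libraries each, and no comparison with separate controls was run, so the source of the excess was not tested. Csf1r was at 10750, 9435 and 7747 CPM in Control, 4wk STZ and 8wk STZ, and mt-Cytb at 4958, 4851 and 2314 CPM.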

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

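The comparison of rods with other retinal cells, both tests on mitochondrially encoded transcripts and the comparisons with the similarity of the 8wk STZ libraries were chosen after the results were seen, while the test of scaling was set before. Cone markers entered the first of these after their values were known, and its reading rests on them.

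Rod transcripts were lower at 8 than at 4 weeks, and lower at both than in Control, by a list median of -0.759 between the times: -0.891 for Rom1, -0.804 for Gnat1 and -0.807 for Pde6g, as list calls not kept with an estimated correlation (adjusted p = 0.408 between the times, and 0.941 and 0.291 against Control), with no rod gene called at 4 weeks. An equal loss of RNA from all other retinal cells would move their markers alike, and against Control at 8 weeks cones lay 1.69 (log2) above rods (SD of members 0.746). Their level less that of rods was -4.46 ± 0.944 in 8wk STZ, against -5.89 ± 0.236 in Control but -4.48 ± 0.413 in 4wk STZ, and -5.59 in 8wk STZ 2. Single cone genes, chosen after their values were seen, show the list to be a weak gauge. Gngt2, at 134 to 221 CPM over all libraries, shares 12.5% of its exonic sequence with Abi3 on the opposite strand. Arr3 and Gnat2 lay at 14.1 CPM or less, and Opn1sw ran from 2.37 to 35.2 CPM within 8wk STZ. The cone values therefore do not settle an equal loss. Medians of bipolar cells (-1.31, SD 0.424), Müller glia (-0.966, SD 0.745) and amacrine, horizontal and ganglion cells (0.948 above the rods, SD 1.49) lay within 1 SD of the rod median of -1.44, so a like loss from these and rods stays open. Other scalings left the rod median at -1.33 or lower, which argues against scaling. Even or uneven loss of free retinal RNA, a change in rods or in their debris inside microglia, and an unrecorded batch stay open. The 8wk STZ libraries form a set of their own (median pairwise r = 0.948), and batch, animal age and diabetes cannot be told apart.

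Mitochondrially encoded transcripts were lower at 8 than at 4 weeks by a list median of -0.985 (adjusted p = 0.408 with an estimated correlation): mt-Cytb -1.07, mt-Co1 -0.985, mt-Co3 -1.03, mt-Atp6 -1.05 and mt-Nd1 -1.14. If the same carried-over retinal RNA as that of the rods were the whole cause, they would have fallen with the rods at 4 weeks, where rods had a median of -0.645 and these transcripts 8.69e-05 (SD of members 0.138). That SD is no spread between animals. By library, their mean log2 CPM was 7.81, 8.10 and 8.36 in 4wk STZ, against 8.01 to 8.18 in Control. Rods were at 7.73, 7.265 and 7.88, against 8.24 to 8.32. A smaller fall at 4 weeks could lie within this spread, so the comparison does not settle that cause. Reads moving to near-identical nuclear copies on chromosome 1 (24611535 to 24616197) would leave the sum in place, and the summed reads of both had a log2 fold change of -0.975. A batch, animal age or 8 weeks of diabetes acting on microglia may be the cause. These cannot be told apart (median pairwise r = 0.948 within 8wk STZ). The lower share of ribosomal RNA genes in the same libraries (1.39% against 2.09% in Control) leaves a difference in library make-up open, which was not tested.

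Other effects differed between the times by a test of the difference itself. Lower at 8 weeks were Eno1 (-0.489), Hk1 (-0.618), Sdha (-0.425), Snap25 (-0.934), Syt1 (-1.18), Vtn (-0.964) and Impg1 (-1.72). Higher were Srsf2 (2.29), Plekhg2 (1.69) and Ccl3 (0.702). Lists that differed had median differences of 0.549 for interferon response, -0.263 for glycolysis, 0.66 for the cell cycle, -0.279 for ribosomal proteins, -0.668 for Müller glia, -1.06 for bipolar cells and -0.914 for amacrine, horizontal and ganglion cells, with adjusted p of 0.408 to 0.642 with an estimated correlation for the 9 lists. In all 18 of 145 genes and 9 of 36 lists were picked out in this way.

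Single 8wk STZ libraries stood apart from the other 3, relative to the range of the 4, in 14 of 206 values tested, and chance flags about 1 in 20 groups. The gap can be small in size, as for Atp6ap2 at 205 CPM in 8wk STZ 2 (others 188 to 190), Glul at 578 CPM in 8wk STZ 1 (others 516 to 523) and Hk1 at 68.2 CPM in 8wk STZ 3 (others 80.7 to 83.0). In 8wk STZ 4 the genes were Ccl9 (117 CPM, others 186 to 198), Nr4a1 (15.4, others 6.13 to 6.41), and the T and NK cell genes Gzma (5.22, others 0.0159 or less) and Lck (3.96, others 0.0802 to 0.619). The mean log2 CPM of the cell cycle list was 3.17 there (others 3.76 to 3.86) and that of the renin-angiotensin list 3.59 (others 1.83 to 2.11). In 8wk STZ 3 they also included Pdgfb (85.9 CPM, others 53.1 to 55.2), Nadsyn1 (3.7, others 7.91 to 8.76) and the share of ribosomal RNA genes (1.83%, others 1.20 to 1.26%). Mx1 was at 49.4 CPM in 8wk STZ 2 (others 18.4 to 22), and the mean log2 CPM of B cell markers at 1.75 in 8wk STZ 1 (others 2.51 to 2.55).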

How the results depend on the processing

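The likelihood ratio test, the thinned libraries and the fit without Control 3 and 4wk STZ 3 were chosen after the data were examined. For the genes that the rule names and the 36 lists, no alternative called a direction opposite to a call; other called genes were not followed gene by gene. The number of genes called against Control at 4 weeks (0) became 12 without a filter, 1 with protein-coding genes only, 492 with DESeq2 and 244 with the likelihood ratio test, and ran from 0 to 1 when a library was left out. At 8 weeks (449) it became 209 with a 2-fold threshold, 1684 with DESeq2, 1166 with the likelihood ratio test and 275 without Control 3 and 4wk STZ 3, and ran from 206 to 255 when a library was left out. Between 8 and 4 weeks (174) it became 69 with a 2-fold threshold, 277 without a filter, 291 with the stricter filter, 100 with only the groups compared, 357 with protein-coding genes only, 1211 with DESeq2, 759 with the likelihood ratio test and 6 without Control 3 and 4wk STZ 3, and ran from 13 to 118 when a library was left out. Fewer libraries or fewer genes tested are part of these settings by construction, and for the others the cause was not tested. Within 1.5 times of the counts at 8 weeks lay RLE (452), library totals (539), upper quartile (488), no filter (506), the stricter filter (591), only the groups compared (463), protein-coding genes (593), 1 surrogate variable (381), limma-voom (514) and thinned libraries (479).

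With an estimated correlation 0 lists passed in each comparison, and with fry 0, 5 and 4, so the list calls depend on the small preset correlation. The lists passing by fry at 8 weeks were those of rods, mitochondrially encoded transcripts, glycolysis, B cells, and amacrine, horizontal and ganglion cells. At 4 weeks the number of lists (2) became 6 without a filter, 5 with limma-voom and 4 without Control 3 and 4wk STZ 3, and between the times (9) it became 14 without a filter. When a library was left out, lists ran from 2 to 5 at 4 weeks, 9 to 14 at 8 weeks and 8 to 13 between the times. The cause was not tested. Library totals moved the median of all genes at 8 weeks by 0.104 (log2), and 66% of the calls made with them were higher than that median. Other scalings and comparisons moved it by 0.0856 or less. Of the called genes that the rule names, 10 of 62 at 8 weeks and 0 of 27 between the times passed in all settings.

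Same-numbered samples of the groups did not deviate together (correlations of -0.0297 to 0.0348), so the replicate numbers name samples and do not pair them. With the replicate number as a block, 44 genes were called at 8 weeks and 0 between the times, and the count at 4 weeks stayed at 0. The correlation of fold changes ran from 0.494 to 0.722 when a library was left out, and was 0.545 with the block. With every library thinned to about the lowest total, 186 genes were called between the times.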

Other observations

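The test of nuclear RNA, the test on further family members and the comparison with library similarity were chosen after results were seen, while the test of GC content and length, apart from its value for these members and its reading, and the counts over other splits were set before.

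The kinases Clk1 and Clk4, which phosphorylate SR proteins, rose at 8 weeks along with Srsf2. Of 16 genes of the SR, CLK and Tra2 families, chosen after the values of 8 of them were seen, these 3 rose and none fell, with a median log2 fold change of 0.343 that this choice can itself raise. Clk4 stood at 50.7 ± 5.40 against 22.8 ± 3.07 CPM in Control and 18.6 ± 4.33 CPM in 4wk STZ, and Clk1 at 162 ± 30.8 against 86.5 ± 12.2 and 98.7 ± 9.56 CPM. Ccnl1 also rose between the times.

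The 8 members not looked at before had a median of 0.242, just above the 95% value of 0.219 (96.4th percentile) of 10000 random lists matched on expression, and none of the 8 was called, so a rise across the family may hold but rests on little. A trend of fold change with GC content and length explained 0.198% of the variance among genes, too little for its removal to be a test. It left a median of 0.286 for the family, above the cut set beforehand, and 0.158 for these 8, below that cut. More nuclear or unspliced RNA could raise such genes, and the test does not settle it: 1440 intronic, antisense and intergenic genes had a median of 0.0263 with an SD of 1.7, and the nuclear RNAs Neat1 and Malat1 lay on opposite sides (log2 fold changes 1.44 and -0.615, adjusted p = 0.0523 and 0.0559). A batch, animal age or 8 weeks of diabetes acting on microglia cannot be told apart here (median pairwise r = 0.948 within 8wk STZ).

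The counts were set beside other splits of the same libraries. At 8 weeks 1 of 35 splits, the real one, gave 449 genes (highest other 0), and between the times 1 of 35 gave 174 (highest other 1). The real split thus ranked first in both, which does not exclude chance. No rank among 35 splits can be lower than 1 of 35, and splits that mix the groups hold their difference as spread, which lowers their counts. For the lists the real split did not rank first: 12 of 35 splits gave 11 or more lists at 8 weeks (highest other 18) and 13 of 35 gave 9 or more between the times (highest other 14). At 4 weeks the 10 splits are too few for a share below 0.05 (genes: real 0, highest other 1; lists: real 2, highest other 9).

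In 4wk STZ, genes with a read after thinning numbered 22810 ± 479.6, and ribosomal RNA genes took 2.08 ± 0.401% of reads. Genes of the retinal pigment epithelium, chosen after their values were seen, stood out in 1 library: Ttr was at 20.6 CPM and Rgr at 28.3 CPM in 8wk STZ 3, against at most 0.851 and 2.18 CPM in the others. The same library had few transcripts of border macrophages, with Mrc1 at 6.9 CPM and F13a1 at 2.51 CPM, against at least 17.7 and 21.1 CPM in each other library. Apoe varied from 5180 to 19400 CPM within 8wk STZ.

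The authors' deposited table calls 1055 genes at 8 weeks (520 higher, 535 lower) and 116 at 4 weeks (54 higher, 62 lower) with a likelihood ratio test at an FDR below 0.05. Of the 449 genes called here at 8 weeks, 443 are in that table, and all 443 are called there in the same direction. That overlap is no separate support. The table rests on the same counts, its log2 fold changes correlate with those here at r = 1, and its test calls more genes. The likelihood ratio test run here on all 18957 genes called 1166 and 244, and the 1166 include all 449.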
